A study of Mus musculus with 6 samples.

How the data were processed

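Polyadenylated RNA of MA1L mouse liver tumour cells was sequenced in 3 libraries of cells transduced with a Kmt2d guide and 3 libraries of cells transduced with a non-targeting vector. Per the labels' protocols, the cells were grown in medium with fetal bovine serum, RNA was extracted with TRIzol, and libraries were made with a polyA-selected Illumina TruSeq v2 kit. The group and replicate number of each library were taken from its title. The submitters' processing notes name kallisto, sleuth, STAR, DESeq2 and the mm10 build, with no role or version, and versions are not given in the sources used here. Whether the libraries keep the strand is not given in the sources used here, so reads of overlapping genes may not be told apart.

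For each library the authors deposited a table with 1 row for each of 88198 transcripts, in the columns that kallisto writes. Per the file headers, these columns are the estimated count of each transcript, its TPM (a count scaled by length and library) and its effective length in bases, and kallisto divides a read that matches several transcripts between them. The authors also deposited a table of their own comparison per transcript, with a p-value and q-value of a Wald test and a difference b on the natural log scale, per the file headers. On 4139 abundant transcripts, b followed the difference of the mean natural log of the deposited estimated counts with a constant offset of 0.00733, so a positive b means higher in sgKmt2d. Values from that table are used only where it is named.

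Estimated counts of a gene's transcripts were summed and rounded to whole numbers. Of the transcripts, 86119 (97.6%) were matched by identifier to the GENCODE M21 annotation of mm10, and 136 more took a gene name from the authors' deposited table. The other 1943 carried no gene and were left out. They held between 0.736% and 0.840% of a library's estimated counts. This gave 30326 genes. The library totals were 18049336, 16983188 and 18217196 estimated counts for sgKmt2d replicates 1 to 3 and 17676821, 19978828 and 16911966 for Vector replicates 1 to 3. Genes near 1 CPM therefore have few counts per library, and counting error is large below that level.

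The 6 libraries were compared in R 4.3.3 with edgeR 4.0.16: filterByExpr with the group and a minimum count of 10 kept 13409 genes, TMM factors ran from 0.995 to 1.005, and the quasi-likelihood test (glmQLFit, glmQLFTest) compared sgKmt2d with Vector with no covariate. P-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. Group means are CPM, counts scaled to the library total, computed with the TMM factors, given as mean ± SD over 3 libraries. The chi-square per degree of freedom of the counts of 2 libraries was 1.64 to 2.35 within groups and 12.6 to 14.1 between groups, so no library repeated another.

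Before the data were examined, 41 gene lists were written for the tissue and the treatment, and 39 had at least 5 measured genes. The lists of erythroid markers (1 measured gene) and sex-linked marker genes (4 measured genes) were too small to test. A list was tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 39 lists. Each was also tested with an estimated correlation and with fry, and its called genes were counted with p-values adjusted over all genes and adjusted over the list alone. A list counts identifiers, so a symbol with 2 identifiers counts as 2 entries (Dlk1 and Srsf1). The lists share few genes, at most 5 between any pair.

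The genes named were fixed by a rule before the data were examined. They are the 10 largest rises and 10 largest falls by log2 fold change among called genes with at least 5 CPM on average and with groups that do not overlap, leaving out unnamed gene models and pseudogenes. They are also up to 4 called genes with the largest change in each list that passed and up to 2 in each other list (at least 1 CPM), all members of the Kmt2d list, and 13 genes of antigen presentation, interferon signalling and the tumour model named whatever their values. Some genes that the rule selects are not reported here. The retained-intron share is the percent of a library's estimated counts on transcripts annotated as retained intron, compared by an exact two-sided permutation test, whose smallest p is 0.1.

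Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no filter on low counts, a stricter filter (a mean of at least 1 CPM and 10 counts in 3 libraries), limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean of at least 1 TPM, effective transcript lengths as an offset, the replicate number as a block, and leaving out each library in turn. A correction for GC content and transcript length (a lowess trend per library with a span of 0.4) was added after seeing the data. For lists, camera then ran on the corrected log2 CPM instead of the counts, so in that setting its input also differed from the main test.

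The tests were checked on simulated counts for 13307 genes drawn from the real mean, dispersion and library sizes, with changes placed in the sgKmt2d libraries. Among 50 genes changed at each size, edgeR recovered 70% of 1.2-fold, 84% of 1.5-fold, 88% of 2-fold and 98% of 4-fold changes, with 20 false calls among 13108 unchanged genes. DESeq2 recovered 58%, 78%, 86% and 98%, with 2 false calls. The recovered genes numbered 35, 42, 44 and 49 for edgeR and 29, 39, 43 and 49 for DESeq2. Set against these, false calls made up a larger share of edgeR's calls than of DESeq2's. For edgeR that share was also larger than its adjusted p threshold aims at. Calls made by edgeR and not by DESeq2 are therefore less certain. Camera called 5 of 5 simulated lists shifted by 0.3 on the log2 scale and 0 of 35 unshifted lists. The simulated genes were drawn independently of each other, so this does not check false list calls from correlated genes. Camera called up to 9 lists when the real libraries were split with the groups mixed. Such splits keep part of the group difference, so they do not count false list calls either. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 prepared the tables, and matplotlib 3.10.9 drew the plots.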

Results

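The data are 6 RNA libraries from MA1L cells, which were grown from a primary mouse liver tumour that lacks p53 and overexpresses Myc. In 3 libraries the cells had been transduced with a guide RNA against Kmt2d (the sgKmt2d group), and in 3 with a vector that targets no gene (the Vector group). Kmt2d encodes a lysine methyltransferase that places methyl groups on histone H3 at enhancers. The libraries held between 16911966 and 19978828 estimated counts, and 13409 of 30326 genes had enough counts to be tested. The labels call the replicates cellular replicates and do not say whether they came from separate transductions. The p-values therefore measure only the spread between these samples, which may be technical, and the guide cannot be told apart from any other difference between the 2 transduced populations.

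The series has 1 comparison, sgKmt2d against Vector, in a study whose title names KMT2D as a modulator of immune checkpoint blockade. It asks which messenger RNAs differ in tumour cells that received the Kmt2d guide. Kmt2d messenger RNA itself, on chromosome 15 from 98831669 to 98871204 (minus strand, mm10), stood at 271 ± 4.93 CPM (estimated counts scaled to the library total; mean ± SD, n = 3) with the guide and 271 ± 9.52 CPM with the vector. The log2 difference was 0.00 with a standard error of 0.03 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.916). A guide that makes small insertions or deletions need not lower the level of the transcript, so this level checks the group labels only in part. In the authors' deposited table, the main protein-coding Kmt2d transcript had a difference of -0.0332 on the natural log scale (q = 0.9998).

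Outside Kmt2d, a large part of the measured transcriptome differed. The fetal growth factor gene Igf2 and the collagen gene Col3a1 rose, and most changed class I antigen presentation genes and type I interferon targets fell. Every gene that passed the test fell in the lists of cholesterol synthesis (21 of 24 genes), glycolysis (13 of 21), fatty acid synthesis and lipid storage (11 of 18) and bile duct markers (5 of 13). As lists, none of these passed camera with an estimated correlation. In all, 5042 genes changed (37.6% of those tested), 2298 upward and 2744 downward, by edgeR's quasi-likelihood test at an adjusted p under 0.05. Most of these changes were small: 419 genes changed at least 2-fold, 93 upward and 326 downward. Limma on log2(TPM + 1) called 1581 genes upward and 1552 downward, with 31 and 126 at least 2-fold. In 6423 genes (47.9%) the 3 sgKmt2d libraries did not overlap the 3 Vector libraries, where chance alone gives 10%. Replicates lay close together, with a common biological coefficient of variation of 2.50%, and the first principal component, with 57.6% of the variance, separated the groups. Across 10067 well-expressed genes the fold changes followed GC content weakly (Spearman -0.256 across genes, which are not independent replicates).

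Igf2, a growth factor of fetal tissues, was the clearest of the large rises. It lies on chromosome 7 from 142650766 to 142666816 (mm10) and stood at 95.4 ± 1.68 CPM in sgKmt2d and 13.7 ± 0.492 CPM in Vector cells (n = 3 each), a log2 change of 2.79 with a standard error of 0.04 (edgeR adjusted p = 7.6e-15). Pappa, a secreted protease that cuts IGF-binding proteins, rose from 18.5 ± 1.18 to 52.4 ± 0.776 CPM (log2 1.51, edgeR adjusted p = 1.8e-11). Col3a1, a fibrillar collagen gene on chromosome 1 (45311538 to 45349706), went from 137 ± 3.95 to 351 ± 7.49 CPM (log2 1.35), Spon1 rose by 1.71 and Fndc1 by 1.38 on the log2 scale. The chemokine gene Cxcl15 rose by 1.38, the organic anion transporter gene Slco1a4 by 2.34 and the protease inhibitor gene Serpinb1a by 1.32 (496 ± 15.7 against 199 ± 2.96 CPM). Wdhd1 had the highest fitted log2 change, 2.97, but its sgKmt2d libraries varied widely (23.2 ± 11.1 CPM against 2.97 ± 1.17 CPM). Its value is uncertain, because 3 transcripts that carry no gene name have the length of a Wdhd1 transcript. When their counts were added, the sums were 49.8 ± 2.00 and 52.2 ± 1.33 CPM.

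Among the largest falls were neighbours on chromosome 1. Prss56, a serine protease gene (87183313 to 87188405), fell from 216 ± 0.164 to 46.3 ± 0.774 CPM, a log2 change of -2.23 with a standard error of 0.03 (edgeR adjusted p = 1.2e-15). Chrnd, which encodes the delta subunit of the muscle acetylcholine receptor, begins just downstream at 87190607 and fell from 15.7 ± 1.48 to 2.31 ± 0.314 CPM (log2 -2.76). Sparcl1 and Dmp1, a pair of matrix-associated genes on chromosome 5, fell by 1.92 and 1.96 on the log2 scale. Gulo, whose enzyme makes vitamin C in mice, had a log2 change of -2.52, and Rdh9, of the retinol dehydrogenase family, -2.59. The receptor tyrosine kinase adaptor gene Grb7 had -2.22, the zinc transporter gene Slc30a2 -2.15, Bpifb4 -2.11 and the signalling scaffold gene Cnksr1 -2.04. The rule that chose these 10 genes required all 3 sgKmt2d libraries to lie below all 3 Vector libraries. The highest edgeR adjusted p among the 10 was 1.2e-07 (Sparcl1). Apart from Prss56, all had under 5 CPM in sgKmt2d cells.

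**Figure D1:**
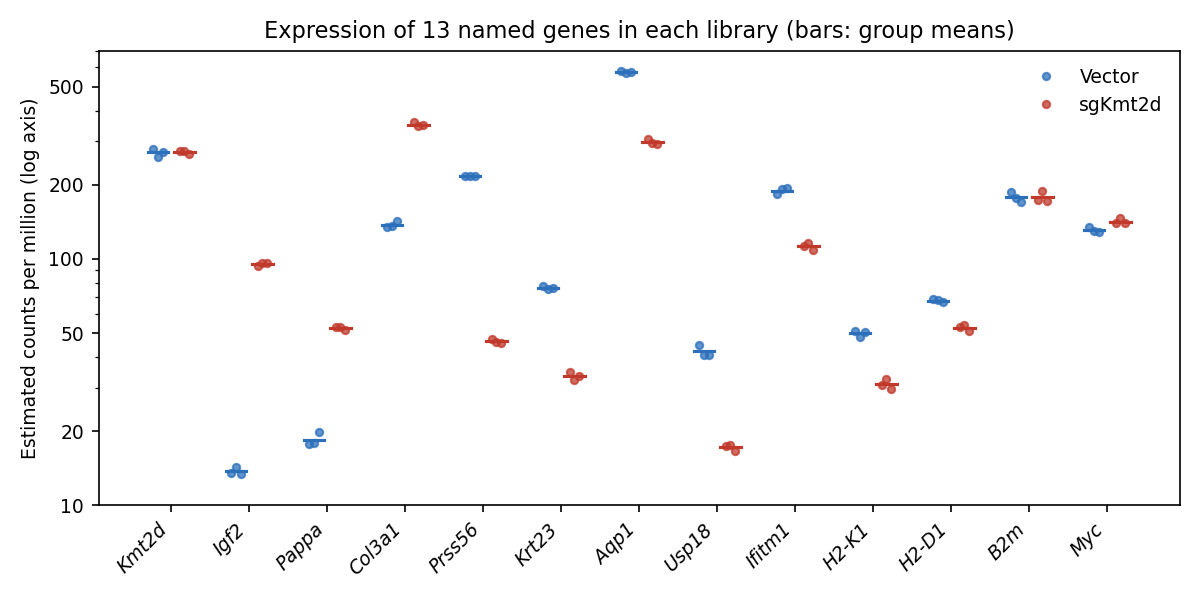
Estimated counts in CPM of 13 named genes (vertical log axis) in each of the 3 Vector libraries (blue points) and 3 sgKmt2d libraries (red points), with a bar at each group mean. Kmt2d and B2m lie at the same level in both groups (271 and 178 CPM), whereas Igf2 rises from 13.7 to 95.4 CPM and Prss56 falls from 216 to 46.3 CPM.

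Genes of the histone H3 lysine 4 methyltransferase complexes changed little. Of 20 measured, 6 rose and none fell by edgeR's quasi-likelihood test (at an unadjusted p under 0.05, 8 were higher and 0 lower, and DESeq2 called 2 higher and 0 lower). Adjusted over the list alone, the counts were 6 and 0. Kmt2b (log2 0.10), Ncoa6 (0.11), Hcfc1 (0.11), Psip1 (0.11) and Kdm6a (0.13) rose by small amounts. The values of Kmt2a (-0.01), Kmt2c (0.08), Setd1a (0.07), Setd1b (-0.03), Kdm6b (0.05), Paxip1 (-0.07), Wdr5 (0.08), Rbbp5 (0.01), Ash2l (0.02), Dpy30 (0.06), Men1 (0.02), Cxxc1 (0.06) and Wdr82 (0.02) did not pass. The list as a whole had a median log2 change of 0.06 (camera adjusted p = 0.142, and 0.569 with an estimated correlation). Pagr1a, the sixth gene that rose, had a log2 change of 2.55 (4.06 ± 0.161 against 0.726 ± 0.747 CPM) that is uncertain, since it overlaps Pagr1b and Gm42742. Pagr1b, named after its values were seen, stood at 0.0507 and 4.19 CPM, and the 3 genes together at 32.9 ± 1.95 and 33.4 ± 1.69 CPM. DESeq2 gave adjusted p values of 0.157 for Pagr1a, 0.112 for Kdm6a, 0.0967 for Kmt2b and 0.0583 for Ncoa6. Psip1 reached 0.0934 in edgeR after a correction for GC content and length. Under that correction Kdm6a also lost its call (0.238), but Wdr5 (0.0182), Cxxc1 (0.0187) and Setd1a (0.0243) gained one. Kmt2c passed with effective transcript lengths as an offset (log2 0.20, edgeR adjusted p = 0.0116). It also passed with limma on log2(TPM + 1) (log2 0.21, adjusted p = 0.0398).

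Genes of the mesenchymal state and extracellular matrix mostly rose, and the bile duct markers that passed the test fell. Of 38 measured mesenchymal and matrix genes, 25 rose, 7 fell and 6 did not pass the test (25 and 9 adjusted over the list alone). Col3a1 (log2 1.35) and the matrix protein gene Tnc (0.82) rose, whereas S100a4, a calcium-binding protein gene often used as a fibroblast marker, fell (-1.11, from 161 ± 3.68 to 74.5 ± 1.54 CPM). The list had a median of 0.15 and was higher relative to all other genes (camera adjusted p = 5.5e-14, and adjusted p = 0.161 with an estimated correlation). Of 13 bile duct markers, 5 fell and 8 did not pass (1 higher and 5 lower adjusted over the list alone). The keratin genes Krt23 (-1.19) and Krt19 (-0.71), the water channel gene Aqp1 (-0.94, from 574 ± 7.05 to 299 ± 7.52 CPM) and Spp1 (-0.73) fell, and the list's median was -0.27 (camera adjusted p = 1.5e-06, and 0.161 with an estimated correlation). Markers of other cell types moved in both directions. Of 11 stellate cell and fibroblast markers, 5 of them shared with the mesenchymal list, 5 rose and 6 fell with the same counts adjusted over the list alone, among them Des at -1.67 (median -0.49, camera adjusted p = 0.531). Des was low, at 0.545 CPM in sgKmt2d and 1.75 CPM in Vector cells. Among 6 measured endothelial markers Kdr rose (0.61) and Flt1 fell (-0.17), with the same counts adjusted over the list alone (camera adjusted p = 0.313). Flt1 missed the threshold with DESeq2 (adjusted p = 0.228). Of 24 immune cell markers only 5 were measured, of which Lyz2 fell (-0.72, under 3 CPM in either group), also adjusted over the list alone (camera adjusted p = 0.802), and missed the threshold with DESeq2 (adjusted p = 0.0505).

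Cholesterol synthesis had the largest share of falls among the metabolic groups by edgeR. Of its 24 genes, 21 fell and 3 did not pass (22 fell adjusted over the list alone), with a median log2 change of -0.20 (camera adjusted p = 9.1e-06, and 0.167 with an estimated correlation). DESeq2 called 18 falls and limma on TPM 11. Most members fell by little. Nsdhl (-0.32), Idi1 (-0.29) and Tm7sf2 (-0.27) encode enzymes of sterol synthesis. In the list of fatty acid synthesis and lipid storage, 11 of 18 genes fell and 7 did not pass, also adjusted over the list alone (median -0.10, camera adjusted p = 0.0019, and 0.204 with an estimated correlation). The lipid droplet coat genes Plin4 (-1.52) and Plin2 (-0.37), Dgat2, which makes triglycerides (-0.80), and the desaturase gene Scd1 (-0.35) led it. Of 21 glycolysis genes, 13 fell and 8 did not pass, also adjusted over the list alone (median -0.11, camera adjusted p = 0.00104, and 0.204 with an estimated correlation). Examples are Aldoc (-1.29), Pfkp (-0.39), Hk1 (-0.31) and the lactate transporter gene Slc16a3 (-0.31). Tm7sf2 missed the threshold with DESeq2 (adjusted p = 0.125).

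Other metabolic and stress lists did not pass camera as a whole in the main test. Of 18 hypoxia targets 3 rose and 5 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.662), with Car9, a carbonic anhydrase gene, at -2.23 and Bnip3 at -0.40. Of 21 targets of NRF2, the regulator of the antioxidant response, 3 rose and 11 fell, also adjusted over the list alone, among them Gstm1 (-0.79, from 286 ± 11.5 to 166 ± 7.72 CPM) and Ces2g (-1.03). That list lay close to the threshold (camera adjusted p = 0.0556), which it passed without sgKmt2d replicate 2 (0.0333) or 3 (0.0448) and without Vector replicate 2 (0.0469) or 3 (0.0491). The integrated stress and unfolded protein response list had 8 rises and 4 falls among 24 genes (8 and 6 adjusted over the list alone, camera adjusted p = 0.589), with Atf3 at -0.89 and Sesn2 at 0.31, and limma on TPM called 5 rises and 2 falls. Oxidative phosphorylation had 2 rises and 10 falls among 44 genes (2 and 7 adjusted over the list alone, camera adjusted p = 0.662), with Sdhd at -0.20 and Cycs at 0.17. DESeq2 called only 0 rises and 3 falls in it, and limma on TPM 1 and 4 (3 and 13 by edgeR at an unadjusted p under 0.05). Of 13 mitochondrially encoded messenger RNAs, 1 rose and 4 fell (2 and 4 adjusted over the list alone, 1 and 2 by DESeq2, 1 and 0 by limma on TPM, camera adjusted p = 0.912). mt-Nd1 (0.11) and mt-Co2 (-0.18) were its named members, and after a correction for GC content and length the value of mt-Nd1 was -0.01 (adjusted p = 0.662).

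Genes of class I antigen presentation and targets of type I interferon fell more often than they rose. Of 22 measured antigen presentation genes, 11 fell, 2 rose and 9 did not pass (11 and 3 adjusted over the list alone), with a median log2 change of -0.26 (camera adjusted p = 0.0019, and 0.167 with an estimated correlation). The classical class I heavy chain gene H2-K1, on chromosome 17 from 33996017 to 34000347, fell from 49.96 ± 1.35 to 31.1 ± 1.48 CPM (log2 -0.68, edgeR adjusted p = 2.6e-08). H2-D1 fell from 67.8 ± 0.835 to 52.6 ± 1.44 CPM (-0.37, edgeR adjusted p = 1.5e-06). The related genes H2-Q6 (-1.14), H2-Q7 (-1.11) and H2-Q4 (-0.89) also fell. Class I genes are near-identical in places, so reads may be divided between them and each gene's own value is uncertain. B2m, which encodes the light chain, stood at 178 CPM in both groups (log2 -0.00, edgeR adjusted p = 0.991), and the peptide transporter gene Tap1 at 5.02 and 5.08 CPM (-0.02, edgeR adjusted p = 0.928). Nlrc5, a regulator of class I genes, was too low to test, with 16 and 22 counts over the 3 libraries of each group.

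Of 24 measured type I interferon targets, 9 fell and 15 did not pass, also adjusted over the list alone (median -0.19, camera adjusted p = 0.0251, and 0.204 with an estimated correlation). Usp18, a negative regulator of interferon signalling, fell from 42.1 ± 2.32 to 17.2 ± 0.543 CPM (log2 -1.29), Ifitm1 by 0.75, Oasl1 by 0.58 and Isg20 by 0.50. DESeq2 called 5 of the list's genes lower and limma on TPM 8, and DESeq2 gave Oasl1 an adjusted p of 0.0876. The interferon gamma list had 2 rises and 5 falls among 21 genes, also adjusted over the list alone (camera adjusted p = 0.621), with Iigp1 at 0.76 and Icam1 at -0.55. That excess of falls was absent with DESeq2 (2 rises and 2 falls) and with limma on TPM (1 and 1). The transcription factor gene Irf1 fell (-0.29), but with effective transcript lengths as an offset its edgeR adjusted p was 0.0556. Of the receptor's 2 chains, Ifngr1 had -0.08 (edgeR adjusted p = 0.193), and with that offset -0.15 (edgeR adjusted p = 0.0486). Ifngr2, named after its values were seen, fell from 62.4 ± 2.10 to 43.2 ± 0.833 CPM (-0.53). Among 6 measured class II genes none passed by edgeR (1 higher and 1 lower at an unadjusted p under 0.05, and 0 by DESeq2 or limma), also adjusted over the list alone (camera adjusted p = 0.780).

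Checkpoint and T cell co-signalling ligands had 3 rises and 7 falls among 16 measured genes (3 and 8 adjusted over the list alone, camera adjusted p = 0.0662). Ceacam1 (-1.41) and Vsir (-0.72) fell. Ceacam1 was low and varied in sgKmt2d cells (0.975 ± 0.506 CPM, against 2.57 ± 0.265 CPM in Vector cells), so its value is uncertain. Cd274, which encodes PD-L1, stood at 2.26 ± 0.326 CPM in sgKmt2d and 3.09 ± 0.464 CPM in Vector cells (log2 -0.45, edgeR adjusted p = 0.0625). This difference did not pass in the main test. In edgeR it passed without Vector replicate 3 (adjusted p = 0.0390) and after the correction for GC content and length (log2 -0.49, adjusted p = 0.0431). Chemokines and cytokines went both ways, with 6 rises and 8 falls among 23 genes, also adjusted over the list alone (camera adjusted p = 0.443), led by Cxcl15 and Il11 at 1.38 each. Il11 was low, at 1.80 CPM in sgKmt2d and 0.691 CPM in Vector cells. NF-kB targets had 3 rises and 4 falls among 16, also adjusted over the list alone (camera adjusted p = 0.912), among them Cxcl1 (0.88) and Tnfaip2 (-0.68), and limma on TPM called 1 rise and 3 falls. Of 14 genes of cytosolic nucleic acid sensing, 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.621). Tmem173, which encodes the adaptor STING, fell from 9.30 ± 0.625 to 4.51 ± 0.446 CPM (log2 -1.04), and the RNA sensor gene Ddx58 had -0.35. Limma on TPM called 0 rises and 2 falls in that list (2 and 5 by edgeR at an unadjusted p under 0.05, 0 and 3 by DESeq2).

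Wnt targets and feedback targets of the ERK kinase pathway fell more often than they rose. Of 17 Wnt targets, 9 fell, 3 rose and 5 did not pass, also adjusted over the list alone (median -0.22, camera adjusted p = 7.4e-05, and 0.310 with an estimated correlation). Tcf7 (-0.66), Apcdd1 (-0.65, from 631 ± 11.1 to 403 ± 3.44 CPM) and Sp5 (-0.53) fell, while Dkk1, a secreted Wnt inhibitor, rose (1.01). Of 17 ERK feedback targets, 9 fell, 2 rose and 6 did not pass, also adjusted over the list alone (median -0.22, camera adjusted p = 0.00186, and 0.204 with an estimated correlation). The ERK phosphatase gene Dusp6 (-0.85), Spry2 (-0.45) and Etv4 (-0.43) fell and the early response gene Egr1 rose (0.68). Notch pathway genes had 3 rises and 5 falls among 12 (4 and 6 adjusted over the list alone, camera adjusted p = 0.0662), with Nrarp at -1.40 and Hes6 at -0.69. Growth factor signalling had 6 rises and 11 falls among 25, also adjusted over the list alone (camera adjusted p = 0.662), with the receptor gene Erbb3 at -1.80 and the ligand gene Areg at 0.90 (4 and 7 by limma on TPM). Erbb3 was low, at 0.776 CPM in sgKmt2d and 2.73 CPM in Vector cells. YAP targets had 6 rises and 7 falls among 18, also adjusted over the list alone (camera adjusted p = 0.859), with Ccn2 at 0.49 and Nuak2 at -0.40 (5 and 3 by DESeq2, 4 and 2 by limma on TPM).

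Most Myc targets and ribosome biogenesis genes that passed the test rose, by small amounts. Of 32, 17 rose, 2 fell and 13 did not pass (19 and 2 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.00357, and 0.204 with an estimated correlation). Limma on TPM called 11 rises and 1 fall. Rrp12 (0.27), Nle1 (0.22), Nolc1 (0.22) and Utp20 (0.20) rose, and Myc itself rose from 131 ± 3.02 to 142 ± 3.74 CPM (log2 0.11, edgeR adjusted p = 0.0077). Myc missed the threshold with effective transcript lengths as an offset (adjusted p = 0.104), and Nle1 with DESeq2 (0.0945). Among 13 measured fetal liver and progenitor entries, 2 rose, 3 fell and 8 did not pass (3 and 3 adjusted over the list alone). That list was higher by camera (adjusted p = 0.00306, and 0.285 with an estimated correlation) and had a mean of 0.19 but a median of -0.01. Igf2 (2.79) and Sox4 (0.39) rose, and Gpc3 (-0.47) and Hmga2 (-0.32) fell. The list's call ended in the setting with a correction for GC content and length (camera adjusted p = 0.751). There camera ran on corrected log2 CPM instead of counts, so the loss cannot be credited to the correction alone. Of 34 hepatocyte markers 13 had enough counts to be tested. Of these, 3 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.850), among them Tat (-1.51) and Foxa2 (-0.91), while Alb (15 and 26 counts per group) and Afp (23 and 20) were too low to test.

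**Figure D2:**
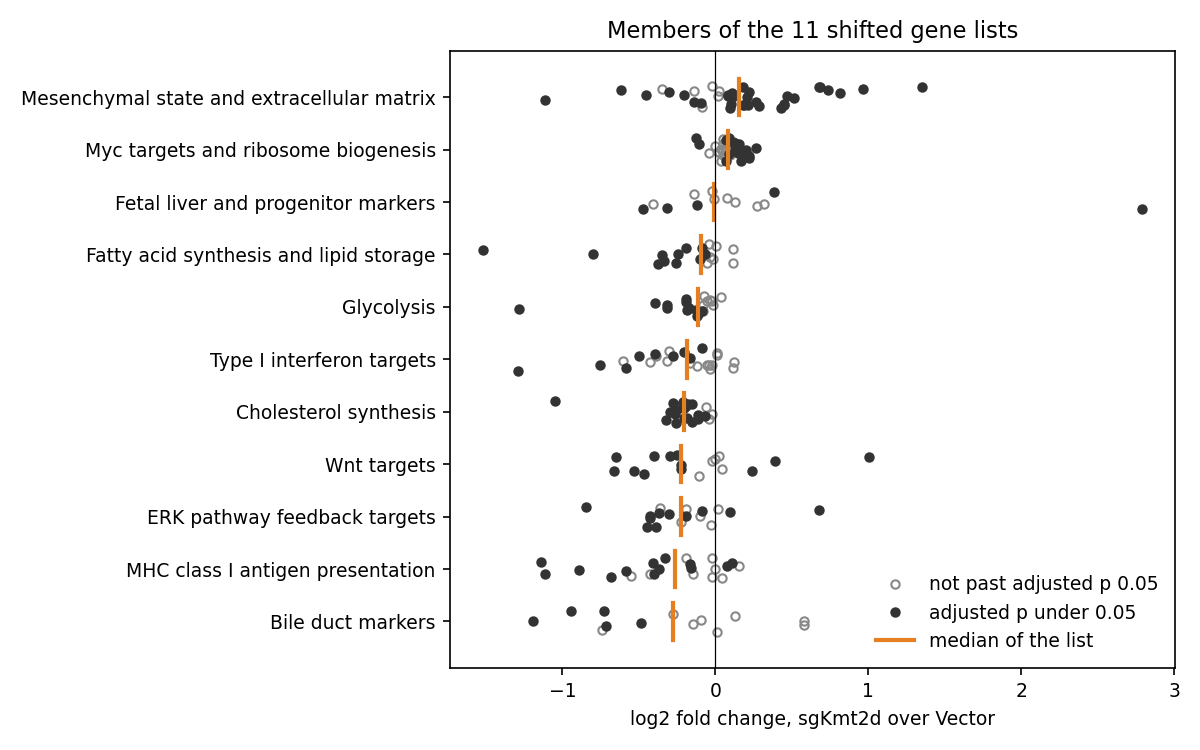
Log2 fold change (horizontal axis, sgKmt2d over Vector) of each measured gene in the 11 lists with a camera adjusted p under 0.05, where filled points passed edgeR's test at an adjusted p under 0.05, open points did not, and an orange bar marks the list's median. Medians run from -0.27 for bile duct markers to 0.15 for mesenchymal and matrix genes, and Igf2 at 2.79 stands far from the other fetal liver genes.

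Cell division, repair and housekeeping lists showed small changes, and none passed camera in the main test. In the setting with the GC and length correction, S phase (camera adjusted p = 0.0106) and G2 and M phase (0.0434) passed as lower. S phase genes had 15 falls and 2 rises among 30, also adjusted over the list alone (median -0.08, camera adjusted p = 0.218), although Ccne1, encoding cyclin E, rose (0.40) and Gins1 had -0.21. DESeq2 called 7 falls and 1 rise in that list, and limma on TPM 5 and 0 (16 and 2 by edgeR at an unadjusted p under 0.05). In the G2 and M phase list 10 fell and 3 rose of 30 (11 and 3 adjusted over the list alone, 3 and 2 by limma on TPM, camera adjusted p = 0.621), with the kinetochore genes Cenpe (0.52) and Cenpf (0.44) among the rises. Of 23 p53 targets, 9 rose and 3 fell (9 and 5 adjusted over the list alone, 5 and 2 by limma on TPM, camera adjusted p = 0.685). Cdkn1a, the cell cycle inhibitor p21, fell from 32.4 ± 0.449 to 15.2 ± 0.282 CPM (log2 -1.10, edgeR adjusted p = 7.1e-10) and the death receptor gene Fas rose by 0.89, in cells described as lacking p53. Trp53 itself stood at 18.3 ± 0.731 and 17.4 ± 1.24 CPM (log2 0.07, edgeR adjusted p = 0.436). Mismatch and base excision repair had 2 rises and 6 falls among 27, also adjusted over the list alone (camera adjusted p = 0.621), with Parp1 at -0.39 (from 421 ± 3.60 to 322 ± 5.76 CPM). Homologous recombination and Fanconi genes had 5 rises and 2 falls among 30 (3 and 2 adjusted over the list alone, camera adjusted p = 0.586), with Brca2 at 0.30 and Fanci at -0.23. DESeq2 called 2 and 2 of these, and limma on TPM 2 and 0 (6 and 3 by edgeR at an unadjusted p under 0.05). Nucleotide excision repair and end joining had 6 rises and 3 falls among 26, also adjusted over the list alone (camera adjusted p = 0.589), with Ercc5 at 0.34 and Xpc at -0.31 (3 and 1 by limma on TPM).

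Of 59 cytosolic ribosomal protein genes, 22 fell and 1 rose, also adjusted over the list alone (median -0.06, camera adjusted p = 0.0915), with Rpl3 at -0.24 and Rpl27 at 0.18, and limma on TPM called 10 falls and 1 rise. This list passed without sgKmt2d replicate 1 (0.0369) or Vector replicate 1 (0.00478). Splicing factors had 9 rises and 2 falls among 44 entries (8 and 2 adjusted over the list alone, 6 and 1 by DESeq2, camera adjusted p = 0.124), with Srsf11 at 0.16; Srsf1 entered under 2 identifiers. Of 32 proteasome subunits 3 rose, Psmd11 (0.10) and Psmb5 (0.09) among them, and 1 fell (camera adjusted p = 0.589). Adjusted over the list alone no proteasome gene passed by edgeR, with 4 higher and 1 lower at an unadjusted p under 0.05 and 0 called by DESeq2. Median, mean and camera's direction differed in sign for the fetal liver, endothelial, stellate cell, hepatocyte, YAP, NF-kB and p53 lists. Of the 39 lists tested, 11 passed camera with its preset correlation, and with a correlation estimated for each list none did (lowest adjusted p = 0.161). Fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, called 29.

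Transcripts annotated as retaining an intron took a larger share of the counts in sgKmt2d libraries. The share was 1.83 ± 0.0142% in sgKmt2d and 1.66 ± 0.0269% in Vector cells (n = 3 each), a difference of 0.166 percentage points over 14089 such transcripts. All 3 sgKmt2d libraries lay above all 3 Vector libraries (exact two-sided permutation test, p = 0.1, the smallest p that 3 against 3 can give). Within 3579 genes that had both retained-intron and other transcripts, the share was higher in sgKmt2d in 68.6%. In 452 of these genes (12.6%) all 3 sgKmt2d libraries lay above the Vector libraries and in 93 (2.60%) below, where chance gives 5% each way. As a share of TPM the difference was 0.268 points.

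**Figure D3:**
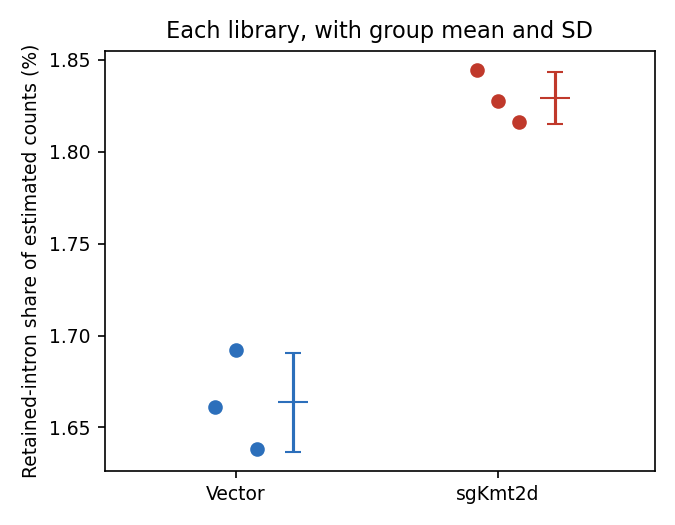
Retained-intron share of estimated counts (vertical axis, percent, not starting at 0) in each Vector library (blue points) and each sgKmt2d library (red points), with the group mean and SD beside them. The groups lie apart, at 1.66 ± 0.0269% and 1.83 ± 0.0142%.

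The authors' deposited table of a Wald test per transcript gives another reading of the same libraries. In the authors' deposited table, 2435 of 37501 transcripts had a q under 0.05, 806 higher and 1629 lower in sgKmt2d. These belong to 2299 genes in the authors' deposited table, of which 2298 were tested here, 2264 were called by edgeR and 2263 had the same direction. Igf2 had a natural log difference of 1.95 (q = 2.1e-65) and Prss56 of -1.55 in the authors' deposited table. There, H2-K1 had -0.480 (q = 3.3e-17) and Cd274 -0.316 (q = 0.625) for their leading transcripts, per the authors' deposited table.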

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

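The tests of scaling, of whole chromosomes, of genomic DNA and of the Wdhd1 reads, and the corrections for GC content and length, were chosen only after the results they bear on had been seen, and of these only the bounds for the GC tests were written before the tested values were seen.

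Besides retained introns, the shares of 5 further classes of transcript, which no other comparison in this text uses as shares, were examined, each class holding at least 0.1% of the counts, and 3 lay above the Vector libraries in all sgKmt2d libraries. Chance gives that in 1 in 20 classes, and shares of 1 total are not independent. Their counterpart is the share of protein-coding transcripts, which lay below the Vector libraries in all sgKmt2d libraries (92.89% against 93.23% on average). Transcripts annotated for nonsense mediated decay were higher by 0.0590 percentage points (1.54 ± 0.0190% against 1.48 ± 0.0119%). The annotation class named processed transcript, kept apart from the protein-coding class and so not a measure of mature messenger RNA, was higher by 0.0420 points (1.43 ± 0.0104% against 1.38 ± 0.0188%). Unprocessed pseudogenes were higher by 0.0399 points (0.272 ± 0.00671% against 0.232 ± 0.0103%).

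The first pattern is the excess of falls among large changes, 326 against 93, a ratio of 3.51. A trend of the libraries on GC content and length is argued against as its whole cause, since the ratio was 3.44 once that trend was removed. A gain or loss of a whole chromosome is argued against by medians of log2 change at most 0.0538 from 0 (chromosome 13) among chromosomes with at least 100 well-expressed genes, while chromosome Y, with 6 such genes, had 0.173. Scaling stays open, because TMM centres most genes near 0 and so fixes the median of all tested genes (0.00321) whatever the cause. Loss of Kmt2d function and a difference between the transduced populations also stay open, and this design does not separate them.

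The second pattern is the higher retained-intron share in sgKmt2d. Removing each library's trend on transcript GC left a difference of 0.148 points, against 0.161 for the same transcripts uncorrected. That a few genes carry it alone is argued against, as 68.6% of 3579 genes had a higher share. The highest of the other 9 splits of the 6 libraries gave 59.3%, which is below the real split but above the bound of 55% written beforehand, so a strict reading of that bound leaves this undecided. The test of genomic DNA written first, whether receptor genes of smell were higher in every sgKmt2d library (27.0 ± 2.24 against 24.6 ± 0.989 CPM), was undecided. A replacement by length gave 13.8% of the difference, also undecided, while it counted detected transcripts only, and 1.43% once that error was mended and all transcripts were counted. Open explanations are slower splicing or RNA decay in sgKmt2d cells and a different share of nuclear RNA in the extracts, for which no test was run.

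The third pattern is the rise of Wdhd1, the highest fitted log2 rise among the genes named. Reads that match both Wdhd1 and transcripts without a gene name may account for it, since adding the 3 such transcripts of equal length (of 1943 without a gene) turned the log2 difference from 2.98 into -0.0654. The sgKmt2d libraries differed in how the reads were divided, with 12.3, 34.5 and 22.8 CPM on Wdhd1. Equal length does not prove identity, and the sequences were not compared.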

How the results depend on the processing

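The correction for GC content and length was the alternative chosen after seeing the data. Across the alternatives, 61 values of the main results stayed within their limits and 7 moved. Of the values of named genes, 1950 stayed on the same side of the threshold, 118 lost the call, 10 gained it and 1 reversed, and for lists the numbers were 426, 12, 28 and 1. A change of direction counted as reversed only where at least 1 of the values compared was called, so values never called may have changed sign. The count of changed genes, 5042, was 3133 (1581 higher, 1552 lower) with limma on log2(TPM + 1) and 3104 (1566 higher, 1538 lower) on log2(TPM + 0.1). The count at least 2-fold changed, 419, was 157 (31 and 126) and 268 (62 and 206). The cause was not tested. DESeq2 called 3458 genes, all among edgeR's and in the same direction, and effective lengths as an offset gave 3602. The other counts were 5064 with RLE factors, 5200 without a filter, 4977 with the stricter filter and 5126 with the GC and length correction. These were not all the same genes: 601 of the 5042 calls were lost with the GC and length correction, and 2111 with limma on log2(TPM + 1). Leaving out a library gave 4232 to 4584 changed genes and 428 to 450 at least 2-fold. Kmt2d was not called under any alternative run, with log2 values from -0.02 to 0.12. The retained-intron difference was 0.268 points as a share of TPM, 0.171 in genes with a coding transcript, 0.159 on transcripts with at least 5 counts and 0.153 to 0.180 without a library.

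The 11 lists called by camera became 0 with an estimated correlation and 29 with fry, 12 without any 1 library and 15 with the GC and length correction. The cause was not tested. For bile duct markers, class I antigen presentation and type I interferon targets the estimated correlation (-0.00049, -0.023 and -0.0080) was below the preset 0.01. A larger correlation between genes is therefore argued against as the cause of their loss. The other called lists had estimates above 0.01, so for them it stays open. With the GC and length correction the fetal liver list lost its call, and the lists of the Kmt2d complexes (0.0304), checkpoint ligands (0.0434), S phase (0.0106) and G2 and M phase (0.0434) gained one. In that setting camera ran on log2 CPM instead of counts, so for lists the correction and the change of input cannot be told apart. The list of mitochondrially encoded messenger RNAs reversed under that correction, from higher (adjusted p = 0.912) to lower (0.00234), as did the named gene mt-Nd1 (-0.0127); the cause was not tested.

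Calls that ended under DESeq2 include Icam1, Psmd11, Psmb5, mt-Co2, Gins1, Cycs and Nuak2. Without a library between 1 and 10 named genes lost their call, among them Flt1, Psmb5, Kdm6a, Kmt2b, Psip1, Tm7sf2, Nuak2, Fanci, Rpl27 and Gins1.

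No sign was seen that the replicate numbers pair the samples. Deviations of same-numbered libraries correlated by 0.06, -0.07 and 0.05, and not every library correlated best with its own number. Such small correlations cannot exclude a pairing. With the replicate number as a block, 4685 genes were called and 416 at least 2-fold, 11 lists passed, Kmt2d stood at 0.00, and the retained-intron difference was 0.166 points (exact paired p = 0.25, the smallest 3 pairs can give).

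Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split is the 1 with the most calls in each case, with 5042 genes changed, 419 changed at least 2-fold and 11 lists. The highest of the other splits gave 0, 0 and 9. Every other split mixes sgKmt2d and Vector libraries on each side, so the group difference widens its spread and its zeros carry little weight. The groups are also unequally mixed, so part of their difference remains between the sides. The 9 lists are therefore not a count of false calls. These zeros are from edgeR, with at most 296 genes at an unadjusted p under 0.05 against 6149 for the real split.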

Other observations

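All tests in the next paragraphs, of the added gene lists and of neighbouring genes, were chosen only after the table of all genes had been seen.

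Epithelial junction and barrier genes may have fallen together in sgKmt2d cells, a hypothesis prompted by the bile duct keratins. Of 23 measured genes outside the lists fixed beforehand, 15 fell and 8 did not pass edgeR's test (median log2 change -0.62, camera adjusted p = 1.7e-07 over 3 added lists, and 0.0117 with an estimated correlation). Among them the serine protease gene St14 fell from 188 ± 3.05 to 104 ± 3.41 CPM (-0.85), Krt18 from 259 ± 4.16 to 149 ± 1.89 CPM (-0.80), Jup, which encodes plakoglobin, by 0.53 and the desmosomal plaque genes Ppl and Pkp2 by 1.43 and 0.38 on the log2 scale. Cdh1, the E-cadherin gene, was already low at 2.87 and 3.19 CPM (-0.15, edgeR adjusted p = 0.490), and Dsp changed little (-0.11).

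Genes of the BMP and TGF-beta pathways may have shifted upward, an idea prompted by large changes among such genes, Bmp7 included. Of 25 genes left after removing the prompting genes and members of the fixed lists, 12 rose and 5 fell (median 0.09, camera adjusted p = 0.0038, and 0.0584 with an estimated correlation). The ligand genes Bmp2 (0.54, 162 ± 2.39 against 111 ± 1.82 CPM) and Inhba (0.81) rose, as did the antagonist genes Fst (0.53), Fstl1 (0.33) and Grem1 (0.32), while Ltbp3 (-0.22) and Chrd (-0.74) fell. The list holds ligands and their inhibitors, so its direction is not that of pathway activity. Bmp7, one of the prompting genes, fell from 51.5 ± 0.396 to 18.3 ± 0.352 CPM.

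Imprinted genes were examined because Igf2 and Plagl1 (0.91) rose. Over all 18 measured entries 7 rose and 2 fell (camera adjusted p = 7.2e-11, and 0.0349 with an estimated correlation). Without the prompting genes and members of the fixed lists, 4 rose and 2 fell of 13, and the list no longer passed (camera adjusted p = 0.0540, and 0.298 with an estimated correlation). Peg10 (0.66) and Mest (0.62) rose and Igf2r fell (-0.10), so whether imprinted genes as a class may have risen stays undecided.

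Neighbouring genes fell together more often than chance gives. Among 320 protein-coding genes that fell at least 2-fold, 16 adjacent pairs with unlike names both fell, against a mean of 6.41 in 10000 permutations of the falls within classes of expression (highest 19, one-sided permutation p = 0.001). Adjacent here means next in order among the 12938 protein-coding genes that entered the test, so other genes may lie between. The widest gap was 121 kb (Rasal1 and Oas1c). Without the 10 largest falls, which prompted the test, 13 pairs remained among 310 genes against a mean of 5.95 (permutation p = 0.007). Examples are Cdkn1a and Rab44 on chromosome 17, Slpi and Matn4 on chromosome 2, and Tuba8 and Usp18 on chromosome 6. Among the 89 genes that rose at least 2-fold there was 1 such pair against a mean of 0.484 (permutation p = 0.4). Shared regulatory elements may underlie the pairs, and reads that run from a gene into its neighbour could do the same for the closest ones, 0.298 kb apart for Slpi and Matn4. Neither was tested.

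The cells of both groups held messenger RNA of fibroblast and of hepatocyte markers, in genes named here after their values were seen. Of 14 stellate cell and fibroblast markers 11 had enough counts to be tested, and of 34 hepatocyte markers 13. Col1a1 stood at 1621 CPM in sgKmt2d and 1425 CPM in Vector cells and Pdgfra at 172 and 241 CPM, but Des only at 0.545 and 1.75 CPM. Among hepatocyte markers Apob stood at 281 and 246 CPM, Ass1 at 82.3 and 59.6 CPM and Foxa1 at 61.4 and 38.4 CPM, whereas Alb and Afp had at most 26 counts over the 3 libraries of a group. Several other tested hepatocyte markers were low, among them Cyp2e1 (2.07 and 2.22 CPM), Hnf4a (1.15 and 0.740 CPM) and Apoa2 (0.887 and 0.740 CPM).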
